A study of Homo sapiens with 52 samples.

How the data were processed

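Gene expression was measured in 52 samples of 6 human tumour cell lines on 1-colour (Cy3) Agilent arrays, with 1 array per sample. The prostate carcinoma lines were DU145 and PC3, the head and neck squamous carcinoma lines were FaDu and Cal33, and the glioblastoma lines were LN229 and U87MG. Per the labels' protocols, photons were 200 kV X-rays given at 1.3 Gy/min, and protons of 150 MeV were given at 3 Gy/min in a spread-out Bragg peak with a dose-averaged linear energy transfer of 3.7 keV/µm. The labels give a range of physical doses from 0 to 8 Gy but no dose for a sample, so the dose behind each array is unknown here and the arms are called sham, photon and proton. The labels give the late samples 7 days beside 420 hours, which do not match, and the value in days was used. They give the 4 h samples 0.07 days beside 4 hours, which do not match either, and the value in hours was used. Per the labels' protocols, the U87MG line held by the repository is of unknown origin.

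Per the file headers, spot intensity was extracted by the authors with Agilent Feature Extraction 10.7.3.1, which gave a background-subtracted and detrended processed signal for each of 62976 spots. The deposited value table is on the log2 scale. Each of its cells equalled the log2 of the median spot intensity plus 1, so it is neither background-corrected nor scaled between arrays, and its array medians lay between 4.81 and 5.91. R 4.0.2 and limma are named in the submitters' processing notes, with no step given, and the submitters' own normalization and test are not given in the sources used here.

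For the values below, log2 of the deposited processed intensity was taken and each array's 75th percentile over the noncontrol spots was subtracted. That percentile lay between 111.7 and 595.7, and 43.6% to 58.7% of the noncontrol spots of an array were well above background by the scanner software. No spot was saturated. The number of arrays and the signal over background limit the precision. Control spots and spots marked as outliers were left out, spots of a probe were averaged, and a probe was kept where it was well above background on every array of at least 1 group. The brightest probe stood for a gene name, which left 26296 gene names, of which 17062 were gene symbols. Of 58201 probes, 31104 received a symbol through their RefSeq accession in a table of the GRCh38.p14 assembly and 27097 did not and kept the name in the file. The arrays were designed on hg19, whose annotation was not used here, so no coordinates are given.

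The labels give 26 groups of a line, an arm and a time. At day 7 each of the 6 lines has sham, photon and proton arrays, 3 per arm in DU145 and PC3 and 2 in the other lines, which makes 14 per arm. DU145 also has 2 photon and 2 proton arrays at 12 h. DU145 and PC3 have 1 array per arm at 4 h. Group means were fitted by least squares in R 4.3.3 and the spread was moderated with limma 3.58.1's empirical Bayes step, over the 46 arrays of the 20 groups with 2 or more arrays, which share one estimate of the spread with 26 residual degrees of freedom. The 846 genes with a left-out spot were fitted on their remaining arrays. Contrasts over lines are means of the 6 within-line differences. They describe these 6 lines and not other tumours. Adjusted p-values are limma's moderated test with Benjamini-Hochberg adjustment within a contrast, at a threshold of 0.05, and the same fit gave an F test of whether an effect differed between lines. The 6 arrays at 4 h were fitted apart, with terms for line and arm and 2 residual degrees of freedom, over 23702 genes.

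A total of 31 gene lists with 884 members, of which 837 were measured, were written before the data were examined, and 1 of them is not reported here. They were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation is given where it ended a call. A list of 38 NF-kB target genes was added after the values were seen. Genes are named by a rule written before the data were examined. For the contrasts over lines it took the 12 largest rises and the 12 largest falls past the threshold with the same sign in all 6 lines. For a line it took the 4 largest rises and falls past the threshold whose groups do not overlap, and for the F tests the 8 smallest p. For 12 h and 4 h it took the 5 largest rises and falls past the threshold, or else the 3 smallest p. For a list it took up to 4 members past the threshold, or else the 2 largest differences. CDKN1A, MDM2, MKI67, CCNB1, ALDH1A1, ALDH1A3 and CD44 were fixed as reference genes. Genes outside the rule are said to be chosen afterwards.

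The labels number the replicates 1 to 3, and their protocols say that the proton beam was available every 3 to 4 months, with more variability between independent repeats. Deviations from the group means were therefore correlated between arrays of a line with the same number, over 25450 genes. All 42 same-number pairs at day 7 exceeded 0.1, with a median of 0.522 and a range of 0.1004 to 0.874. In the 4 lines with 2 arrays per arm the deviations mirror each other, so replicates 1 and 2 give the same value and 24 of the 42 pairs hold 12 distinct values. The 12 h pair gave 0.497, while arrays with other numbers in DU145 and PC3 gave -0.653 to 0.274. The numbers were therefore taken to pair the samples. The fit with cell line by replicate number as a block (18 residual degrees of freedom) is given beside a result as the paired value. In DU145 and PC3 each replicate number at day 7 had its own slide, and in the other lines most arms of a replicate shared a slide. These correlations therefore cannot tell paired cultures from arrays of a shared slide. The block also joins the 12 h and day 7 arrays of a number in DU145, a pairing that was not checked. The fit without the block had been fixed as the first one before the data were examined. Nothing in the labels says more on how the repeats were grown, and p-values measure the spread between these samples.

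The arrays lie on 7 slides, and the file headers name 2 scanners. The third repeats and the 4 h arrays were scanned on the second scanner. Most slides hold several arms of a line, so slide was tested as a fixed block and list medians were also computed within each slide. All 52 arrays correlated best with an array of their own line, and replicates correlated at 0.9562 to 0.9899 across 25508 probes. The scanner software marked 2 arrays for evaluation. One was DU145 photon replicate 1 at day 7, with 1531 non-uniform spots, and the other was PC3 photon at 4 h, the array with the lowest percentile.

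The fits were tested on simulated data with 200 genes changed, 50 at each of 4 sizes. For photon versus sham over 6 lines, over 26296 genes, 48% of changes of 0.5 on the log2 scale were recovered, 76% of changes of 1 and 100% of changes of 2. For a line with 3 arrays per arm, 6%, 30%, 64% and 92% of changes of 0.5, 1, 2 and 3 were recovered, and for a line with 2 arrays per arm 6%, 16%, 66% and 94%. The 4 h fit, over 23700 genes, recovered 0%, 2%, 70% and 100%. In the same 4 simulations 16, 4, 8 and 11 unchanged genes passed. The F test found 171 of 200 genes shifted by 3 in 1 line, and camera found the 1 list that was shifted. In all of these simulations the noise was drawn independently for each gene and array with the fit's moderated spread. They therefore lack deviations shared by replicates or genes, and the shares recovered in the real arrays may differ. In the real 4 h arrays CXCL8 did not pass after protons at a mean difference of 3.85. Alternatives covered background correction, normalization between arrays, the deposited value table, the filter, the probe rule, an additive model, the replicate and slide blocks, the correlation between genes, the arrays in the fit, and left-out arrays, replicates and lines. Splits of the arrays were compared with at most 100 regroupings each. Software was data.table (1.17.8), statmod 1.5.0 and matplotlib 3.10.9.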

Results

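Messenger RNA levels were compared between sham-treated, photon-irradiated and proton-irradiated cells of 6 human tumour cell lines. The study's stated purpose was to compare the effects of proton and photon irradiation on several tumour lines. Of the 52 arrays, 42 were taken 7 days after irradiation, 4 at 12 h (DU145 only, photon and proton) and 6 at 4 h (DU145 and PC3, 1 array per arm and line). Values are log2 signals relative to each array's 75th percentile, differences are irradiated minus sham or proton minus photon, and errors are standard errors of the fit. The upper-quartile signal of an array ranged from 111.7 to 595.7 intensity units, and between 43.6% and 58.7% of its spots were well above background.

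At day 7 after photon irradiation, genes of inflammation and the acute phase were among the largest rises in the mean over the 6 lines. The naming rule required the same sign in every line, so that sign is no separate result, and the values in DU145 were small for UBD (0.40), CXCL8 (0.19) and SAA2 (0.24). UBD, a ubiquitin-like protein induced by inflammatory cytokines, rose by 2.07 ± 0.33 on the log2 scale (adjusted p = 0.0025, 13 photon and 14 sham arrays) and the neutrophil chemokine CXCL8 by 2.04 ± 0.45 (adjusted p = 0.028, 14 arrays per arm). Complement C3 rose by 1.85 ± 0.35 (adjusted p = 0.01), the iron-binding acute-phase protein LCN2 by 1.74 and the serum amyloid genes SAA2 and SAA1 by 1.69 and 1.58. The line values of C3 spanned 0.61 to 4.96 and those of SAA2 0.24 to 5.59. The interleukin-33 receptor IL1RL1 rose by 1.96, the protease inhibitor SPINK1 by 1.93, C11orf96 by 1.91, the ubiquitin ligase NEURL3 by 1.82, the phospholipase PLA2G4C by 1.68 ± 0.24 and complement factor CFB by 1.59. Several of these were dim in sham cells, where UBD was well above background on 2 of 14 arrays against 8 of 13 after photons, so their sizes are uncertain.

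Genes of chromosome structure and mitosis were among the largest falls in the mean over the 6 lines after photons. KIF11, a motor of the mitotic spindle, fell by 0.46 on the log2 scale (SE 0.08, adjusted p = 0.0058), the spindle-pole protein ASPM by 0.43, the kinetochore protein SPC24 by 0.46 and the nuclear lamina protein LMNB1 by 0.47. The histone genes H2AC11, H3C2, H3C4, H3C7, H2AC13, H3C10, H2AC4 and H3C8 gave -0.61, -0.55, -0.53, -0.51, -0.51, -0.50, -0.43 and -0.42. Histone genes are near-identical paralogs, so which member a probe measured is uncertain. In all, 171 of 26296 genes changed, of which 93 rose and 78 fell (limma). With the replicate number as a block, 3142 genes changed, of which 1177 rose and 1965 fell, and with slide as a block 1755 changed. The count was 0 without replicate 1, 1 without replicate 2, 510 without replicate 3 and 80 without the DU145 photon array that the scanner software marked. Under quantile normalization 125 rose and 46 fell, and with the deposited values 51 rose and 3 fell.

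The gene lists showed both movements. Of 42 mitotic genes, all 42 had a negative difference after photons and 8 fell, or 33 when adjusted over the list alone (median -0.29, camera adjusted p = 1.7e-28, and 0.0065 with an estimated correlation). Of 43 DNA replication and S-phase genes 6 fell, or 30 adjusted over the list alone (median -0.27, adjusted p = 4.6e-24, and 0.047 with an estimated correlation, but 0.11 with the replicate block as well). Among 36 homologous recombination and Fanconi genes FANCC fell by 0.31, and 11 fell when adjusted over the list alone (median -0.19, adjusted p = 1e-06, and 0.047 with an estimated correlation, but 0.15 with the replicate block as well). Of 37 genes secreted by senescent cells 5 rose, all of them chemokines, and 13 rose adjusted over the list alone. CXCL3 gave 2.04, CCL20 1.84 and CXCL1 1.54 (list median 0.61, adjusted p = 4.6e-24, and 0.0065 with an estimated correlation). Across the 7 slides the median of the mitotic genes lay between -0.49 and -0.02, that of the S-phase genes between -0.47 and -0.10 and that of the secreted genes between 0.33 and 0.85.

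The apoptosis and immediate early lists also kept their call after photons with an estimated correlation. Of 30 apoptosis genes 4 rose, or 7 adjusted over the list alone, with BIRC3, an inhibitor of apoptosis, at 1.41, the pro-apoptotic BCL2-family genes BBC3 and PMAIP1 at 0.84 and 0.70 and the death receptor TNFRSF10B at 0.29 (adjusted p = 0.00023, and 0.027 with an estimated correlation). BIRC3 acts against the process that names the list. Of 23 immediate early genes the stress-induced transcription factor ATF3 rose by 1.48, and 6 rose adjusted over the list alone (median 0.29, adjusted p = 7.7e-10, and 0.049 with an estimated correlation). Within the 7 slides the medians of apoptosis genes ran from -0.07 to 0.12 and those of immediate early genes from 0.06 to 0.49.

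For the lists below the call after photons was lost with an estimated correlation. Of 46 interferon-stimulated genes, 45 had a positive difference, ISG20, an RNA-degrading antiviral exonuclease, rose by 0.74 and 19 rose adjusted over the list alone (median 0.68, adjusted p = 1.3e-27, and adjusted p = 0.075 with an estimated correlation). The within-slide medians of that list spanned -0.04 to 1.43. HLA-F rose by 0.50 among 15 MHC class I genes, of which 5 rose adjusted over the list alone (median 0.22, adjusted p = 5.1e-08, and adjusted p = 0.078 with an estimated correlation). Of 28 unfolded protein and ATF4 response genes ATF3 and DDIT3 rose, and 9 rose and 1 fell adjusted over the list alone (median 0.17, adjusted p = 2.9e-06, and adjusted p = 0.10 with an estimated correlation). Of 48 replication-dependent histone genes 7 fell and H2BC12 rose by 0.41, with 17 falling and 3 rising adjusted over the list alone (median -0.22, adjusted p = 8e-09, and adjusted p = 0.18 with an estimated correlation). Among 43 histone methylation enzymes the H3K27 demethylase KDM6B rose by 0.62 while the H3K36 methyltransferases NSD2 and NSD1 gave -0.34 and -0.23, with 2 up and 6 down adjusted over the list alone (adjusted p = 0.018, and adjusted p = 0.20 with an estimated correlation).

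No member of the following lists changed over all genes after photons, except the elastase inhibitor PI3, which rose by 1.90 among the 25 epidermal differentiation genes (2 rose adjusted over the list alone, adjusted p = 6e-05, and adjusted p = 0.12 with an estimated correlation). The 32 oxidative phosphorylation genes had a median of -0.16 (5 fell adjusted over the list alone, adjusted p = 1.1e-11, and adjusted p = 0.066 with an estimated correlation) and the 39 ribosomal protein genes one of -0.12 (0 adjusted over the list alone, adjusted p = 2.7e-06, and adjusted p = 0.40 with an estimated correlation). The 17 base excision repair genes (median -0.13, adjusted p = 0.018), 29 epithelial genes (0.11, 0.0052), 30 mesenchymal genes (0.03, 0.04) and 27 lysosome genes (0.06, 0.0014) passed as lists, with 0 members adjusted over each list alone. Their adjusted p = 0.095, 0.16, 0.42 and 0.23 with an estimated correlation. Lists that did not pass were non-homologous end joining (median -0.14, adjusted p = 0.063), aldehyde dehydrogenases (-0.15, 0.087), cancer stem cell markers (0.02, 0.18), NRF2 targets (-0.09, 0.30), hypoxia and glycolysis (0.01, 0.07) and cholesterol biosynthesis (-0.07, 0.087). The marker lists of squamous (0.00, 0.094), glial (0.09, 0.32), prostate (0.12, 0.07), leukocyte (0.03, 0.17), endothelial (0.07, 0.07) and fibroblast cells (-0.03, 0.85) did not pass either. The fibroblast median and mean were negative while the test pointed up. With the replicate block 23 lists passed in place of 19.

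Proton irradiation moved many of the same groups at day 7. C11orf96 rose by 2.07 ± 0.40 (adjusted p = 0.014, 14 arrays per arm), complement C3 by 1.96 ± 0.35 (adjusted p = 0.0061), the elastase inhibitor PI3 by 1.95 ± 0.30 (adjusted p = 0.0014) and UBD by 1.84 ± 0.32 (adjusted p = 0.0061). In sham cells UBD was well above background on 2, SAA2 on 4 and PTGS2 on 5 of 14 arrays, so the sizes of their rises are uncertain. NEURL3 rose by 1.84, SPINK1 by 1.80, SAA2 by 1.78, the prostaglandin synthase PTGS2 by 1.71, SAA1 by 1.67, PLA2G4C by 1.62, the calcium-binding protein S100P by 1.56 and ATF3 by 1.46, although the 4 probes of ATF3 spanned 0.01 to 1.46. The kinesins KIFC1 and KIF11 fell by 0.44 and 0.43 on the log2 scale and the kinetochore scaffold KNL1 by 0.43 (SE 0.07, adjusted p = 0.0026). LMNB1 gave -0.50, the pseudogene HMGB3P1 -0.46, and the histone genes H2AC11, H3C2, H3C4, H3C7, H3C10, H2AC13 and H3C8 gave -0.63, -0.54, -0.53, -0.50, -0.49, -0.48 and -0.45. The pseudogene and the histone genes share sequence with near-identical copies and are uncertain.

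Protons changed 144 genes over the 6 lines, of which 81 rose and 63 fell (limma). With the replicate block 2799 changed, 1105 rising and 1694 falling, and with the slide block 1520. The count was 1 without replicate 1, 1 without replicate 2 and 295 without replicate 3. Under quantile normalization 114 rose and 37 fell, and with the deposited values 50 rose and 8 fell.

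After protons the mitotic genes had a median of -0.29, with 9 of 42 falling, or 33 adjusted over the list alone (adjusted p = 1e-30, and 0.0055 with an estimated correlation, but 0.058 with the replicate block as well). The S-phase genes had the same median, with 5 of 43 falling, or 31 adjusted over the list alone (adjusted p = 1.3e-26, and 0.044 with an estimated correlation, but 0.11 with the replicate block as well). FANCC fell by 0.28 among the homologous recombination and Fanconi genes, of which 2 fell adjusted over the list alone (median -0.17, adjusted p = 1.5e-07, and 0.044 with an estimated correlation, but 0.13 with the replicate block as well). Of the 37 secreted genes 5 rose, or 14 adjusted over the list alone, with CXCL8 at 2.17, CCL20 at 2.13, CXCL3 at 2.02 and CXCL2 at 1.53 (median 0.52, adjusted p = 9e-24, and 0.007 with an estimated correlation). Within slides the medians ran from -0.40 to -0.04 for mitotic genes, -0.40 to -0.12 for S-phase genes, -0.26 to 0.01 for the recombination genes and 0.16 to 0.88 for the secreted genes.

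Other lists passed after protons but lost the call with an estimated correlation. ISG20 rose by 0.80 among the interferon-stimulated genes, of which 22 rose adjusted over the list alone (median 0.64, adjusted p = 6.4e-25, and adjusted p = 0.087 with an estimated correlation), and HLA-F by 0.52 among MHC class I genes, of which 5 rose adjusted over the list alone (median 0.21, adjusted p = 1.3e-07, and adjusted p = 0.087 with an estimated correlation). ATF3 and the phosphatase DUSP1, at 0.59, rose among immediate early genes, 8 adjusted over the list alone (median 0.33, adjusted p = 7.5e-10, and adjusted p = 0.053 with an estimated correlation). ATF3, DDIT3 at 0.81 and the chaperone DNAJB9 at 0.34 rose among unfolded protein and ATF4 genes, 10 up and 1 down adjusted over the list alone (median 0.21, adjusted p = 1.3e-06, and adjusted p = 0.087 with an estimated correlation). BIRC3 rose by 1.34 among apoptosis genes, 6 adjusted over the list alone (median 0.06, adjusted p = 0.0021, and adjusted p = 0.053 with an estimated correlation). Of the 48 histone genes 7 fell, with 17 down and 3 up adjusted over the list alone (median -0.24, adjusted p = 9.9e-11, and adjusted p = 0.13 with an estimated correlation). KDM7A rose by 0.62 and NSD2 gave -0.33 among histone methylation enzymes, 2 up and 4 down adjusted over the list alone (adjusted p = 0.02, and adjusted p = 0.20 with an estimated correlation).

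Oxidative phosphorylation genes had a median of -0.16 after protons (6 fell adjusted over the list alone, adjusted p = 9.9e-12) and ribosomal protein genes one of -0.11 (0 adjusted over the list alone, adjusted p = 3.2e-06), with adjusted p = 0.065 and 0.40 with an estimated correlation. The epidermal list, with PI3, had a median of 0.20 (3 rose adjusted over the list alone, adjusted p = 0.00024, and adjusted p = 0.14 with an estimated correlation). Base excision repair (median -0.12, adjusted p = 0.023), epithelial (0.17, 0.00063), mesenchymal (0.14, 0.0013), lysosome (0.10, 5.2e-05) and hypoxia genes (0.06, 0.027) passed with 0 members changed over all genes, and 1 base excision gene and 1 mesenchymal gene rose adjusted over the list alone. Their adjusted p = 0.097, 0.087, 0.22, 0.14 and 0.40 with an estimated correlation. End joining (-0.13, 0.14), aldehyde dehydrogenase (-0.12, 0.38), stem cell (0.02, 0.36), NRF2 (-0.09, 0.21), cholesterol (-0.04, 0.36), squamous (0.02, 0.36), glial (0.03, 0.21), prostate (0.05, 0.17), leukocyte (0.01, 0.13), endothelial (0.03, 0.52) and fibroblast genes (0.02, 0.42) did not pass.

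Among the genes fixed as references, CCNB1, the cyclin of mitotic entry, fell after photons and protons by 0.31 (adjusted p = 0.029) and 0.29 (adjusted p = 0.038). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, had differences of 0.78 and 0.76, positive in 6 of 6 lines, with adjusted p = 0.10 and 0.12, and passed with the replicate block (adjusted p = 0.0017 and 0.0021). The proliferation marker MKI67 had -0.39 and -0.41 (adjusted p = 0.38 and 0.37, and 0.0011 and 0.00081 with the block). MDM2, a ubiquitin ligase, had 0.05 and -0.05, ALDH1A1 -0.21 and -0.13, ALDH1A3 -0.23 and -0.21 and the stem cell marker CD44 -0.03 and -0.08, none of which passed. The sign of CD44 turned under quantile normalization, and that of MDM2 after protons turned in the deposited table.

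**Figure D1:**
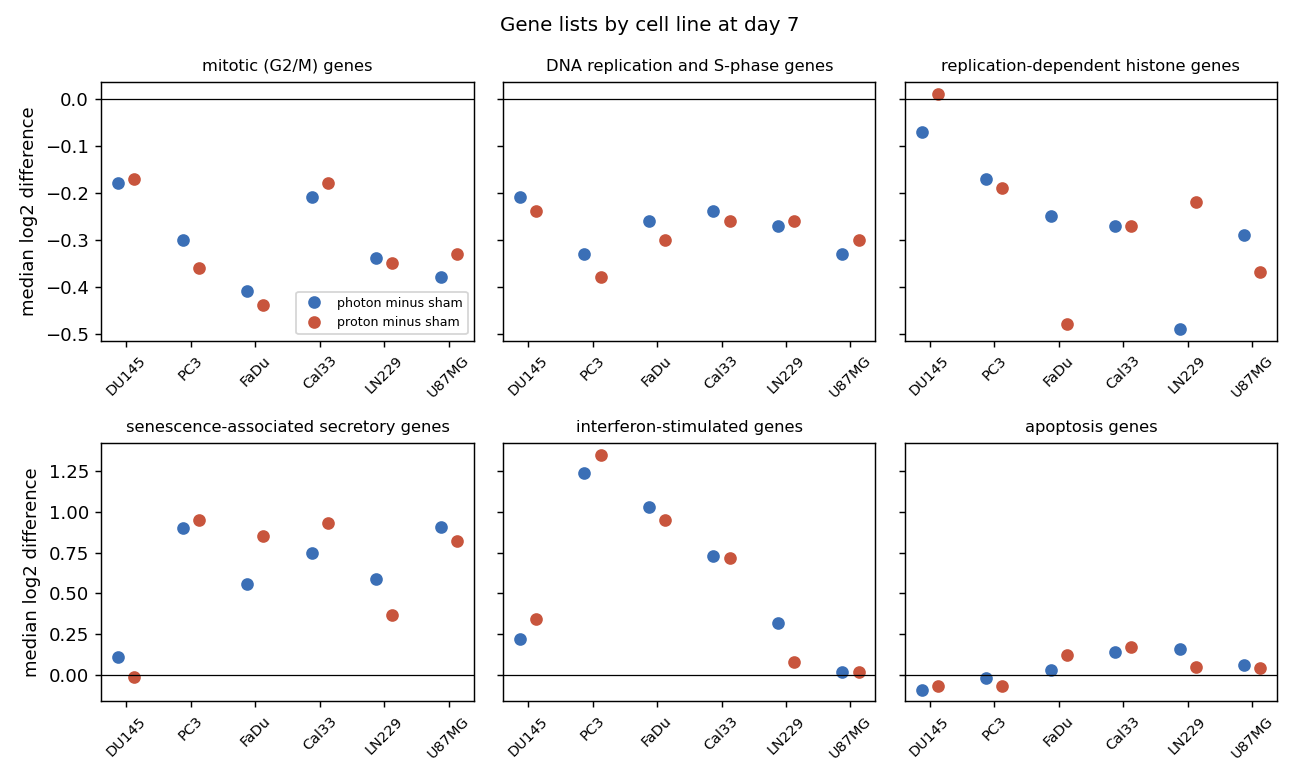
Median log2 difference from sham (vertical axis) of 6 gene lists in each of the 6 cell lines (horizontal axis) at day 7, with photons in blue and protons in red and each point the median over the measured genes of a list. Mitotic genes lay below 0 in every line with both beams, between -0.41 and -0.18 after photons. After photons interferon-stimulated genes ranged from 0.02 in U87MG to 1.24 in PC3, and after protons they had 1.35 in PC3.

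The photon and proton effects were then set against each other. Of 171 and 144 changed genes, 108 were shared in the same direction, 58 rising and 50 falling, and 0 in opposite directions, as the plot of proton against photon effects shows. Independent lists of these sizes would share 0.287 and 0.187 genes. Both comparisons use the same sham arrays, so these are not the values to be had without an effect. With the sham arrays split between the beams, the overlap fell to 3 of 15 and 4 calls, or 2 of 9 and 6 calls. The splits leave fewer sham arrays behind each effect. In 50 simulations without an effect 0 genes were shared, and the effects correlated at 0.509 at most. The observed correlation was 0.836, and that in the splits was 0.217 and 0.265. The observed covariance beyond the simulated mean was 0.0198, against 0.0161 and 0.019 in the splits, where the beams share no array. The splits follow the replicate number and the simulated noise was independent between arrays, so deviations shared by replicates shift these values and their sizes are uncertain. The positive covariance in the splits argues against shared sham arrays as the only source of the overlap. The replicate block gave 2210 shared genes, and without the marked DU145 photon array there were 70.

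**Figure D2:**
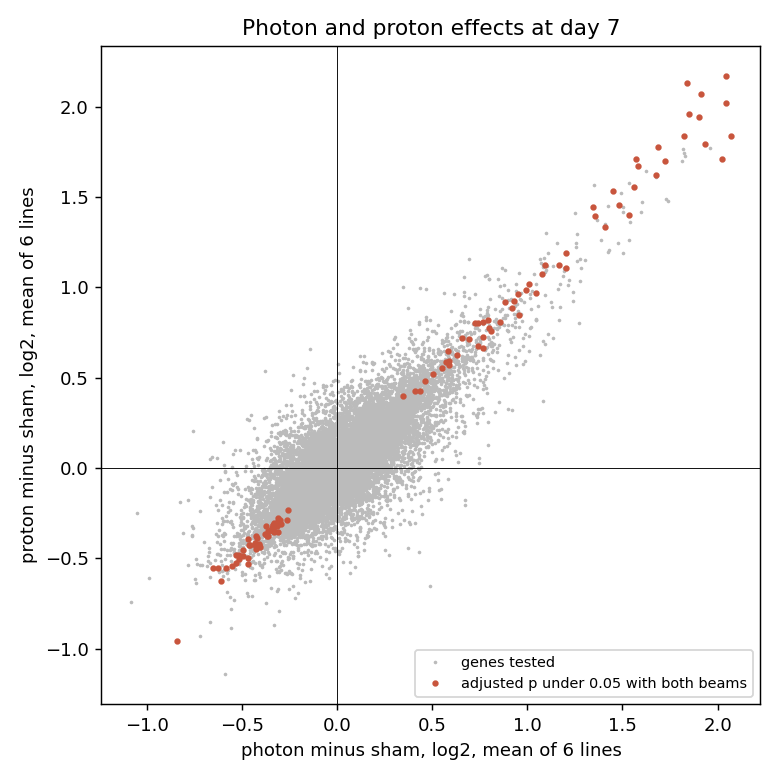
Mean log2 difference from sham over 6 lines at day 7 for each gene tested, with photons on the horizontal axis and protons on the vertical axis. Red points are the 108 genes past the threshold with both beams, all of them in the same direction, and grey points are the genes tested.

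Compared directly over the 6 lines, protons and photons differed in 0 genes by limma, with 136 at an unadjusted p under 0.05. With the replicate block 0 genes passed, with 776 at an unadjusted p under 0.05, and with the slide block 0. CDKN1A, MKI67 and CCNB1 did not pass, and 0 of 31 gene lists passed, against 1 with any replicate number left out and 2 without LN229. The extremes were the endothelial markers (median -0.10, adjusted p = 0.16) and the mesenchymal genes (median 0.05, adjusted p = 0.27). A difference that did not pass does not show that the beams act alike.

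Within single lines, the largest rises were seen in Cal33. After photons SAA2 rose by 5.59 ± 0.87 (adjusted p = 0.0021) and C3 by 4.96 ± 0.91 (adjusted p = 0.014), and after protons by 5.46 and 4.86. CCL20, a chemokine of epithelial inflammation, was not well above background in sham cells and was at least 14.36-fold higher after photons (adjusted p = 0.028) and also higher after protons, at least 14.01-fold. PDZK1IP1, a membrane protein, was at least 18.39-fold and 16.23-fold higher. These bounds set the mean of the bright group against the mean of the dim group, with each dim array raised to the lowest signal called well above background on it. The homeobox gene LHX6 fell by 2.00 and ZNF667 by 0.94 after photons. In total 23 genes changed in Cal33 after photons, 20 up and 3 down, and 16 after protons, all up, against 215 and 266 with the replicate block and 54 and 62 with the slide block. Leaving out 1 array gave 3 genes at the lowest after photons (without photon replicate 2) and 6 after protons (without proton replicate 2). Under quantile normalization 34 genes rose and 4 fell after protons.

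In LN229 the thyroid hormone carrier TTR was at least 6.7-fold higher after photons (adjusted p = 0.0077), the transcription factor CASZ1 at least 4.7-fold and the potassium channel subunit KCNF1 at least 2.67-fold (adjusted p = 9.7e-07), all 3 being not well above background in sham cells. TSGA10IP rose by 2.59. After protons KCNF1 was at least 1.56-fold higher (adjusted p = 0.00061), and SLC16A1-AS1, named after its value was seen, at least 3.49-fold. SLC16A1-AS1 was also higher with protons than with photons by 1.67 ± 0.27 (adjusted p = 0.022), the single gene of that comparison, which had 0 genes with normexp, without the filter on dim probes and without photon replicate 2. Photons changed 11 genes, 10 up and 1 down, and protons 2, against 242 and 83 with the replicate block and 94 and 18 with the slide block. Without photon replicate 1 the photon count was 4, and without photon replicate 2 it was 32. Under quantile normalization 50 genes rose and 15 fell after photons.

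In PC3 S100P rose by 3.00 ± 0.57 after protons (adjusted p = 0.042), the amino acid oxidase IL4I1 by 2.75 ± 0.50 (adjusted p = 0.037) and PLA2G4C by 2.58, while TNFAIP6, a hyaluronan-binding protein induced by TNF, was at least 1.6-fold higher than in sham cells, where it was not well above background. Protons changed 14 genes in PC3, all up (515 with the replicate block, 124 with the slide block), and the count was 0 without proton replicate 3. Photons changed 0 genes by limma, with 906 at an unadjusted p under 0.05, 191 with the replicate block and 38 with the slide block. In U87MG the potassium-chloride cotransporter SLC12A7 rose by 2.49 ± 0.32 after photons (adjusted p = 0.00057) and 2.57 ± 0.32 after protons (adjusted p = 3e-04). Protons also lowered 1 transcript without a gene symbol. LGALSL was at least 1.02-fold higher and SEPTIN6 at least 1.14-fold lower with protons than with photons in U87MG, and each was well above background on only 1 array. The replicate block gave 66, 54 and 9 genes for the 3 comparisons in U87MG, and the slide block 14, 11 and 7.

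In FaDu photons raised 1 transcript without a gene symbol and protons raised LOC728392 at least 1.93-fold, against 60 and 269 genes with the replicate block and 13 and 49 with the slide block. DU145 had 0 changed genes by limma after photons and after protons, with 634 and 560 at an unadjusted p under 0.05, 23 and 1 with the replicate block and 10 and 1 with the slide block. Proton against photon gave 0 genes in DU145, PC3 and FaDu by limma, with 216, 173 and 220 at an unadjusted p under 0.05 and 2, 1 and 2 with the replicate block. It gave 1 probe without a symbol in Cal33 and 1 gene in LN229 (9 and 33 with the replicate block). With a fit on the arrays of each line alone, every count within a line at day 7 was 0.

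The lists moved in most lines, as the plot of list medians by line shows. The secreted genes passed after photons in all 6 lines, with medians of 0.11 in DU145, 0.90 in PC3, 0.56 in FaDu, 0.75 in Cal33, 0.59 in LN229 and 0.91 in U87MG, and after protons in every line but DU145, where the median was -0.01. With an estimated correlation the adjusted p for photons was 0.48, 0.067, 0.28, 0.04, 0.19 and 0.051 in the same order, and for protons it was 0.035 in PC3, 0.10 in FaDu, 0.027 in Cal33, 0.63 in LN229 and 0.073 in U87MG. Mitotic genes had medians between -0.41 (FaDu) and -0.18 (DU145) after photons and between -0.44 and -0.17 after protons. Interferon-stimulated genes had medians of 1.24 in PC3 and 1.03 in FaDu after photons and did not pass in U87MG (0.02). Over the 3 comparisons of a line, 31 list calls were made in DU145, 34 in PC3, 32 in FaDu, 32 in Cal33, 33 in LN229 and 14 in U87MG. With an estimated correlation 0, 2, 1, 4, 2 and 4 list calls were made.

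An F test asked whether the radiation effect, photon and proton arrays together against sham, differed between lines. It found 7 genes, 6 of them with symbols. KCNF1 was at least 2.04-fold higher in irradiated LN229 cells (adjusted p = 0.00014), and SLC12A7 had 2.53 in U87MG, where 1 of 2 sham arrays was well above background, and at most 0.76 elsewhere (adjusted p = 0.011). The others were high in irradiated Cal33 cells, namely the thiolase ACAA2 of fatty acid oxidation at least 1.64-fold (adjusted p = 0.0062), the growth factor NRG2 at least 2.53-fold (adjusted p = 0.011), the nicotinamide methyltransferase NNMT at least 1.68-fold (adjusted p = 0.013) and the polymeric immunoglobulin receptor PIGR at least 10.26-fold (adjusted p = 0.013). KCNF1 in LN229 and these 4 genes in Cal33 were not well above background in sham cells. ACAA2 and NNMT were well above background on 2 and 3 of 4 irradiated Cal33 arrays. BIRC3 (adjusted p = 0.056) and ZNF667 (adjusted p = 0.078) came next and did not pass. The replicate block gave 331 genes and the slide block 50, and the count was 0 without replicate 1 or replicate 2. The proton minus photon difference varied between lines in 0 genes by limma, with 127 at an unadjusted p under 0.05, 6 with the replicate block and 4 with the slide block.

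At 12 h, where DU145 had 2 photon and 2 proton arrays on 1 slide and no sham, the mitotic genes were higher after protons than after photons. All 42 had a positive difference (median 0.38, adjusted p = 7.8e-36, and 0.0022 with an estimated correlation, but 0.055 with the replicate block as well), while 0 passed over all genes. At day 7 the DU145 median was -0.01, and the difference between the 2 times was 0.39, positive for 42 of 42 (adjusted p = 9.8e-24, and 0.022 with an estimated correlation, but 0.22 with the replicate block as well). Cholesterol biosynthesis genes had a median of 0.23 at 12 h, positive for 23 of 25 (adjusted p = 1.4e-06, and adjusted p = 0.76 with an estimated correlation). The proton-photon contrast at 12 h gave 0 genes by limma, with 234 at an unadjusted p under 0.05 and 4 with the replicate block, and the change of that contrast with time 0, with 204 and 3. The smallest p at 12 h belonged to FAM83E, RBBP8NL and the helicase PIF1, the last with 1.01 ± 0.28 (adjusted p = 1), and for the change with time to NME5, CLHC1 and TTYH2, the last 2 with -1.78 and -1.35.

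Irradiated DU145 arrays at 12 h and at day 7 differed in 63 genes, 27 higher and 36 lower at 12 h. All arrays at 12 h lay on 1 slide, which held no DU145 array of day 7. Time and slide are therefore not told apart within this line. With slide as a block, where the slide effect rests on other lines, 70 genes changed. The replicate block joins 12 h and day 7 arrays of the same number, a pairing across times that was not checked. The pancreatic protease gene CTRC was higher by 2.17 ± 0.41 (adjusted p = 0.013), the neuronal microtubule protein MAP2 by 1.52, and the calcium-binding protein CASQ1 at least 1.48-fold. CD79A, a B cell receptor component, was lower, with -0.78 ± 0.14 (adjusted p = 0.011), and PODNL1 was at least 1.02-fold lower. FBXL7 and ADAMTS4 passed but were not well above background on any of these arrays, and UPF3A, CXCL6 and PAX8 passed but were not well above background at 12 h, so no fold is given for them. With normexp background correction the difference of CXCL6 turned to 0.09 and that of PAX8 to 0.10. Lists higher at 12 h were unfolded protein genes (0.36, adjusted p = 0.00056), ribosomal protein genes (0.24, adjusted p = 0.00058) and glial markers (0.94, adjusted p = 0.012), and lists lower were mitotic (-0.06, adjusted p = 0.00058) and histone genes (-0.10, adjusted p = 0.00012), each with adjusted p = 0.73 with an estimated correlation. The replicate block gave 1617 genes, and without photon 12 h replicate 1 and replicate 2 the counts were 221 and 8.

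At 4 h, DU145 and PC3 arrays after protons showed high levels of inflammatory genes beside sham and photon arrays, with no gene past the threshold and no replicate within a line. CCL20 was higher than in sham by 4.94 in DU145 and by at least 4.56 on the log2 scale in PC3, where sham was not well above background (adjusted p = 0.27). CXCL8 was 3.52 and 4.18 higher and the NF-kB target BIRC3 2.77 and 2.87 higher (mean 2.82 ± 0.27, adjusted p = 0.27). Among genes chosen after their values were seen, the cytokine gene CSF2 had a mean difference of 4.41, IL6 3.54, the NF-kB inhibitors TNFAIP3 and NFKBIA 2.49 and 2.07, and ATF3 2.32. TRAF1, a signal protein of the TNF receptors, was 2.81 higher in DU145 and at least 2.95 higher in PC3. CDKN1A was 1.80 and 2.75 higher in DU145 and PC3 (adjusted p = 1). Against photon arrays the mean differences were 2.94 for BIRC3 and 3.40 for CXCL8 (adjusted p = 0.56). The PC3 photon array was the dim one that the scanner software marked. On it CSF2, CXCL8 and TNFAIP3 were higher than in sham by 1.53, 1.00 and 0.56. BIRC3, NFKBIA, IL6, ATF3 and CDKN1A gave -0.29, -0.15, -0.10, -0.29 and -0.10 there. In DU145 after photons CSF2, CXCL8 and TNFAIP3 gave -0.09, -0.10 and -0.27.

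By limma 0 genes changed at 4 h in photon versus sham, proton versus sham and proton versus photon, with 300, 736 and 1333 at an unadjusted p under 0.05. With normexp background correction 3, 74 and 89 passed, and with a fit over all 52 arrays 1, 19 and 231. The smallest p for photons belonged to GPR37L1, AMHR2 and PDGFRB (adjusted p = 0.99), which were well above background on 0, 1 and 1 of the 2 sham arrays and all of which turned negative in the deposited value table, where the median of all genes lay at -1.95 for photon versus sham in PC3. Against 10000 random lists matched on expression, the secreted genes (21 measured) had medians of 0.57 in DU145 and 1.62 in PC3 after protons, both at the 100 percentile, and the immediate early genes (22 measured) 0.70 and 0.63, also at 100. The mitotic genes had -0.20 and -0.41, at the 0 percentile. After photons the secreted genes had 0.02 and -0.07, at the percentiles 65.62 and 46.93, the immediate early genes 0.03 and -0.40, at 70.93 and 0.54, and the mitotic genes -0.02 and -0.26, at 4.34 and 6.78. Camera over both lines gave adjusted p = 4.6e-21 for the secreted genes and 1e-12 for the immediate early genes after protons, and adjusted p = 0.55 with an estimated correlation for both.

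**Figure D3:**
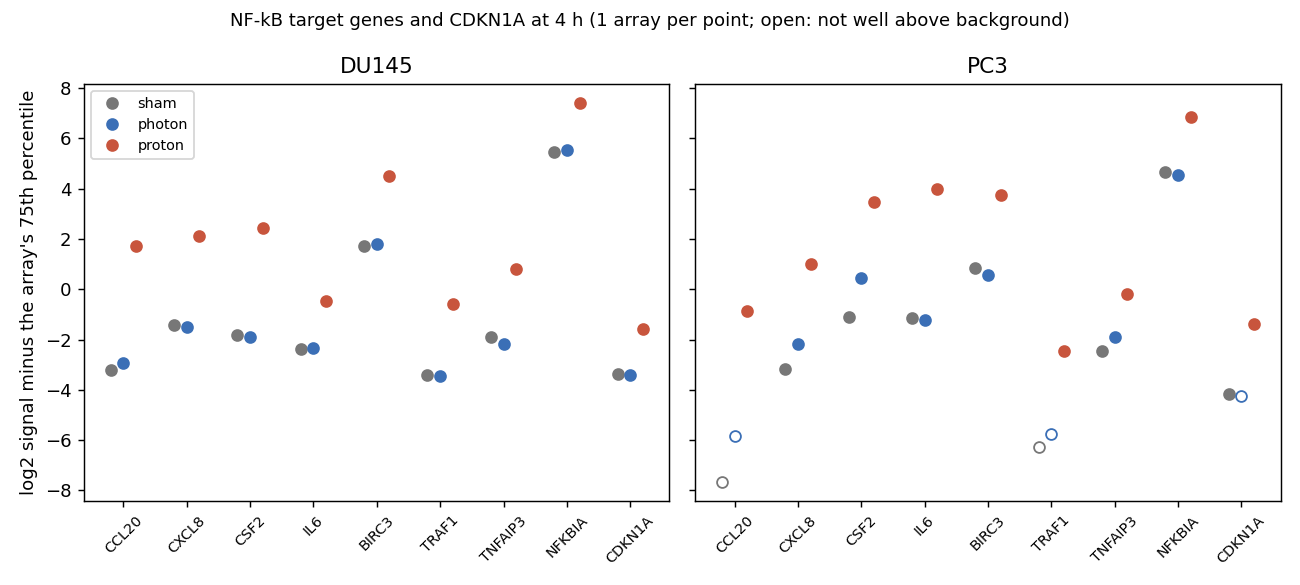
Log2 signal minus the array's 75th percentile (vertical axis) of 9 genes (horizontal axis) at 4 h in DU145 and PC3, with 1 point per array in grey for sham, blue for photon and red for proton, and open points not well above background. The proton array lay above the sham array for each gene, by 4.94 for CCL20 and 1.80 for CDKN1A in DU145.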

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

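The splits of the arrays and, among the technical explanations, scaling and slide at 4 h in PC3, scaling in DU145 at day 7, and the deviating array and scaling at 12 h were chosen before the results were seen, and the NF-kB list and the other tests after them. A difference between groups, by a test of the difference itself, marked 3 results. The radiation effect at day 7 differed between the lines in 7 genes. The NF-kB target genes differed between DU145 and the other 5 lines by a median of -0.74. The mitotic genes of DU145 differed by a median of 0.39 in the proton-photon contrast between 12 h and day 7.

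After protons at 4 h, 31 measured NF-kB target genes had medians of 1.11 in DU145 and 1.94 in PC3, each with 30 of 31 positive, and -0.02 and -0.22 after photons. The list was written after CCL20, CXCL8 and BIRC3 had been seen, so it is circular for them. As the whole list was added after the values were seen, its medians are no independent test of an NF-kB response. The dim PC3 photon array takes no part in the proton-sham difference, whose lower value was 1.11, and the lowest value over 5 other settings was 0.86. In DU145 the 3 arrays shared 1 slide, where the median was 1.11, while for PC3, whose proton array lay on another slide, day 7 arrays gave a slide difference of 0.36 in sham and 0.07 and 0.13 in photon and proton arrays, with PC3 on 1 slide and DU145 on the other, so that slide and line are mixed. Since there was 1 array per line and arm, a slide difference in PC3 and handling or culture of the proton samples remain open readings. A different dose between the beams, which is unknown here, remains open too. They stand beside an early NF-kB response. At 12 h the list in DU145 had a proton minus photon median of -0.20, with 2 of 37 positive (camera p = 2e-05, and p = 0.12 with an estimated correlation).

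At day 7 the NF-kB target genes had a median of 0.67 after photons and 0.81 after protons over the lines, positive for 37 of 37, but of -0.04 in DU145, against 0.35 in LN229, 0.68 in FaDu, 0.73 in PC3, 0.79 in U87MG and 0.99 in Cal33. The difference of DU145 from the others was -0.74 (adjusted p = 1.5e-34 by camera, and 0.0025 with an estimated correlation, 0.014 with the replicate block as well). The list was written after the values were seen, DU145 had the lowest of the line medians, and the adjustment was over lists and not lines. These p-values therefore describe the difference and are no independent test of it. Without the marked photon array, that is for protons against sham, the DU145 median was -0.05, within the arrays of the first scanner it was -0.20, and its highest value over 5 other settings was -0.03. In each of these 3 checks the DU145 median stayed negative, so none of them brought it to the level of the other lines. The lowest median of another line was 0.22 after protons, in LN229, and 0.24 over the other settings. A smaller late response of DU145 and a different dose in it, which is unknown here, were not told apart.

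The mitotic genes at 12 h had a proton-photon median of 0.38, which was not seen at day 7. With 1 of the 4 arrays left out it ran from 0.28 to 0.50, with a replicate pair alone it was 0.29 or 0.48, and its lowest value over 5 other settings was 0.32. The 4 arrays lay on 1 slide, so a slide difference does not separate the arms. At 4 h, with 1 array per arm, the proton-photon median of the mitotic genes in DU145 had the opposite sign (-0.20, with 2 of 42 positive). A different course of the cell cycle after the beams is a biological reading, but no sham array at 12 h shows which arm moved. A different dose between the beams, which is unknown here, was not told apart from it. The 12 h call did not pass with both the replicate block and an estimated correlation (camera adjusted p = 0.055).

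In splits of the arrays over 6 lines, chance was made unlikely, though not excluded, for photons (171 genes, at most 6 in any other of 100 splits, so 1 split as large with the real one included) and protons (144, at most 9, again 1). Chance was not made unlikely for the radiation F test (7, up to 786, 24 as large). For proton against photon (0 genes, up to 65) and the proton-photon F test (0, up to 401) all 100 splits were as large, which a real count of 0 brings by itself, so these splits test nothing. Splits with 786 and 401 genes point to a structure of the samples, since they do not keep replicate pairs together, and among 51 splits that did the highest were 8 and 0. For 12 h against day 7 in DU145 (63 genes) 4 of 100 splits were as large, the highest with 493, which points to such a structure too. Within lines the splits were too few, 10 each. For DU145 the real counts were 0, 0 and 0 and the highest others 4, 1 and 5 for photon, proton and proton against photon, with 10 as large in each case. For PC3 they were 0, 14 and 0 with 344, 15 and 26, and 10, 3 and 10 as large.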

How the results depend on the processing

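The direction of a called gene list turned in none of the settings tried, and the apoptosis, immediate early, mitotic and secreted lists after photons and the secreted list after protons passed in all 19 of them. Over 120 gene values and all settings, 801 comparisons kept direction and side of the threshold, 237 lost the call, 54 gained one and 24 turned sign. Of the counts, 226 stayed within 1.5 times the value given above and 227 did not. The subtraction of the percentile from the deposited table, the replicate block with an estimated correlation, the list totals per line, the median spot signal as the input of normexp and the omission of the marked or the dim array were chosen after seeing the data, and all else was planned. Few arrays per arm and probes near background may limit the small counts, which was not tested. Where a single array is left in an arm, it is assumed to vary like the other groups. The cause was not tested for any value below.

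With normexp background correction the count of genes was 113 for photons over 6 lines, 4 in PC3 and 0 in FaDu for photons, 6 in FaDu and 0 in LN229 for protons, and 0 in Cal33, LN229 and U87MG for proton against photon. It was 29 for 12 h against day 7, 11 for the radiation F test, and 3, 74 and 89 for the 4 h contrasts of photon with sham, proton with sham and proton with photon. MDM2 turned to 0.12 after protons, and at 12 h CXCL6 turned to 0.09 and PAX8 to 0.10. Under quantile normalization photons gave 9 in PC3, 8 in FaDu, 42 in Cal33, 65 in LN229 and 25 in U87MG, protons 23 in FaDu, 38 in Cal33, 22 in LN229 and 9 in U87MG, and proton against photon 6 in Cal33, 4 in LN229 and 8 in U87MG. At 12 h it gave 4 for proton against photon, 2 for the change with time and 106 against day 7, and the F tests gave 55 and 3. CD44 turned to 0.09 after photons and 0.03 after protons.

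In the deposited value table photons gave 54 genes over 6 lines, 2 in PC3, 0 in FaDu, 44 in LN229 and 2 in U87MG, and protons 58 over 6 lines, 6 in PC3, 6 in FaDu and 8 in LN229. Proton against photon gave 3 in Cal33, 0 in U87MG and 1 at 12 h, 12 h against day 7 gave 111, the radiation F test 21 and the overlap 44. At 4 h it gave 2 for proton against sham and 9 for proton against photon. CD44 turned to 0.02 after photons and MDM2 to 0.15 after protons, CCNB1 and ALDH1A3 to -0.01 for proton against photon, and at 4 h GPR37L1, AMHR2 and PDGFRB to -0.08, -0.08 and -0.26. The median of all genes in that table was -0.25 for 12 h against day 7 (0.09 in the values used), 0.19 for LN229 photons (-0.08), and at 4 h -0.14 and -0.16 in DU145 and -1.95 and -0.81 in PC3 for photons and protons. It was 0.16 and 0.15 for PC3 at 4 h with normexp. After subtraction of the percentile the table gave 4 in PC3, 0 in FaDu and 2 in U87MG for photons, 0 in FaDu and 1 in LN229 for protons, 0 in Cal33 and 0 in U87MG for proton against photon, 34 for 12 h against day 7, 12 for the F test, 35 and 31 for protons at 4 h, and 0.13 for MDM2 after protons. The split at 12 h was then 22 higher and 12 lower, against 13 and 98 in the unscaled table. Without a filter on dim probes the counts were 41 for photons and 39 for protons over 6 lines (30 rising and 11 falling, 30 and 9), 13 for Cal33 photons, 1 for PC3 protons, 0 in LN229 and 1 in U87MG for proton against photon, 31 for 12 h against day 7 and 28 for the overlap.

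With the replicate block photons gave 3142 genes over 6 lines and 23, 191, 60, 215, 242 and 66 in DU145, PC3, FaDu, Cal33, LN229 and U87MG, protons 2799 and 1, 515, 269, 266, 83 and 54, and proton against photon 2, 1, 2, 9, 33 and 9. The 12 h contrasts gave 4, 3 and 1617, the F tests 331 and 6 and the overlap 2210. The count of 1617 rests on a pairing of 12 h with day 7 arrays that was not checked. The block also let the end joining, aldehyde dehydrogenase, hypoxia and prostate lists pass after photons (adjusted p = 0.025 each), and over the 6 lines it changed no other call of a list at the preset correlation. With slide as a block the same lines gave 1755 and 10, 38, 13, 54, 94 and 14 for photons, 1520 and 1, 124, 49, 62, 18 and 11 for protons, and 1 in DU145, 1 in PC3, 5 in Cal33, 4 in LN229 and 7 in U87MG for proton against photon. At 12 h it gave 3 for proton against photon and 1 for the change with time, the F tests gave 50 and 4 and the overlap was 1173. ALDH1A1 and ALDH1A3 turned to -0.13 and -0.06 for proton against photon.

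With an estimated correlation 7 lists passed after photons and 4 after protons, and 0 list calls were left in DU145, 2 in PC3, 1 in FaDu, 4 in Cal33, 2 in LN229 and 4 in U87MG, while the replicate block with that correlation left 6 and 1, and the MHC class I and epidermal lists passed after photons (adjusted p = 0.038 each). An additive model over lines gave 666 genes for photons and 690 for protons. With the mean over all probes of a gene, ALDH1A1 and CD44 turned to 0.02 and 0.10 after photons, MDM2 and CD44 to 0.05 and 0.10 after protons, and MKI67 and ALDH1A1 to 0.02 and -0.13 for proton against photon. Without PC3, FaDu, Cal33, LN229 or U87MG photons gave 49, 58, 92, 38 and 64 genes and protons 26, 17, 54, 80 and 69, and without LN229 proton against photon gave 2 lists. With a fit on the arrays of a line alone, 12 h against day 7 gave 3 genes and each other count above 0 in a line became 0, a fit with fewer arrays. These were PC3 protons and, with either beam, FaDu, Cal33, LN229 and U87MG, and proton against photon in Cal33, LN229 and U87MG. Without the marked DU145 array photons gave 80 genes and the overlap was 70. With the sham arrays split the overlap was 3 or 2. A fit over all 52 arrays gave 1, 19 and 231 genes at 4 h.

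Leaving out 1 replicate, photons over 6 lines gave 0 to 510 genes, protons 1 to 295, the F tests 0 to 28 and 0 to 4, proton against photon 1 list each time and the overlap 0 to 241. CD44 after photons spanned -0.06 to 0.02, and for proton against photon CDKN1A spanned -0.13 to 0.15 and MKI67 -0.08 to 0.04. Photon counts ran from 0 to 3 in DU145, 0 to 6 in PC3, 0 to 3 in FaDu, 3 to 30 in Cal33, 4 to 32 in LN229 and 1 to 11 in U87MG. Proton counts ran from 0 to 11 in PC3, 0 to 3 in FaDu, 6 to 17 in Cal33, 2 to 9 in LN229 and 1 to 13 in U87MG. Proton against photon ran from 0 to 1 in DU145 and FaDu, 0 to 7 in Cal33, 0 to 9 in LN229, 0 to 2 in U87MG and 0 to 1 at 12 h, and 12 h against day 7 from 8 to 221.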

Other observations

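These values were chosen after they were seen. Between the beams, lists in single lines passed at the preset correlation of camera only. In LN229 the interferon-stimulated genes had a proton minus photon median of -0.32 (adjusted p = 0.00094, and adjusted p = 0.90 with an estimated correlation) and the secreted genes one of -0.33 (adjusted p = 0.0026, and adjusted p = 0.90 with an estimated correlation). In FaDu the secreted genes had a median of 0.29 (adjusted p = 0.0049, and adjusted p = 0.98 with an estimated correlation).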
